A study of Mus musculus with 16 samples.

How the data were processed

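Gene expression was measured in glomeruli, the filtering units of the kidney, of mouse embryos at embryonic day 18.5. Glomeruli were separated with magnetic beads after perfusion, per the labels' protocols, and their RNA was hybridised to Affymetrix mouse exon arrays. The 16 deposited samples are 2 summaries of the same 8 arrays, so n was 4 per genotype throughout and never 8. Genotypes and replicate numbers were taken from the labels, which give the wild type and a wt1(+KTS) mutant on a mixed C57Bl6 and DBA2 background. The labels do not give the zygosity of the mutants, the litters or the sex of the embryos. The labels also hold a letter at the end of each sample code whose meaning is not given, and no letter occurs in both genotypes. Within each genotype, a single array has a letter of its own and the other arrays share a letter. Differences by genotype therefore cannot be told apart from whatever the letter marks.

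The authors deposited log2 values from RMA, a background correction, quantile normalization and summary of the probes, made with Partek on the mouse build mm9, per the submitters' processing notes. Versions and settings are not given in the sources used here. The base of the logarithm was inferred from the range of the values, from 3.57 to 14.9 over both tables. The gene level holds 93623 transcript clusters and the exon level 375483 probe sets, each with 8 columns. RMA pulls dim probes toward a common floor, so log2 differences of dim genes understate the true ones. Quantile normalization of probes can hide a change in the total amount of RNA. The deposited arrays still differed in their medians, from 5.99 to 6.18 at the gene level and 6.76 to 6.88 at the exon level. Array data have no read depth; the number of arrays limits the precision.

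Gene symbols came from the platform annotation. At the gene level 20707 clusters had 1 symbol, 1349 had several and 71567 had none. At the exon level 192914 probe sets had 1 symbol, 1399 several and 181170 none. Symbols were updated through a RefSeq gene table of GRCm38 for 165 clusters and 25401 probe sets. That build differs from the authors', so the table served only for names and for the order of genes along a chromosome. Rows with several symbols or none were tested but not named. Probe sequences were not used here, so members of gene families with similar sequences, such as Sprr2f, Sprr2g, Gsdmc2, Slc22a30, Cd59b and H2-Aa, are uncertain where a probe binds more than 1 member.

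Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, mutant minus wild type, two-sided), with Benjamini-Hochberg adjustment over every row of a table and a threshold of 0.05. A row past it is called higher or lower. No further scaling, filter or covariate was applied. Exon usage was tested with limma's diffSplice on probe sets with 1 symbol, a mean at or above the table's 50th percentile and at least 3 probe sets per gene. Its F test was the main one. A usage value is the log2 difference of a probe set relative to its gene. For the lists, 25 were fixed before the data were examined and tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera on an estimated correlation and fry beside it. Each gene was represented by its cluster of highest mean. Members are counted past the threshold over all rows and adjusted over the list alone. Several genes of the fixed lists were not analysed here.

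The genes named in the text were chosen by a rule fixed before the data were examined. It takes Wt1, then the 12 largest positive and 12 largest negative differences among called clusters with 1 symbol and no overlap between the genotypes. It adds, in each list described, up to 4 members of smallest p and every called member, and for exon usage Wt1 and the 10 genes of smallest F-test p with their most deviating probe set. In the podocyte list, 1 called member is counted but not described. Genes named outside that rule are marked as chosen after their values were seen.

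Each step was tested on simulated data with known changes. Of rows changed 1.5-fold, 4% were called at the gene level and 0% at the exon level. Of rows changed 2-fold, 36% were called at the gene level (93623 rows) and 20% at the exon level (375483 rows), and of those changed 4-fold, 82% and 72%, and 8-fold, 100% and 94%. Unchanged rows made up 2.63% and 3.13% of the calls. Of the lists, 1 shifted by −0.3 had a camera adjusted p of 1.08e-39. Camera called 0 others, not counting the lists on podocytes, WT1 targets, basement membrane, actin and angiogenic signals. The simulated noise was independent between genes, so this does not test camera where genes of a list are correlated. In the real arrays, regroupings into 4 and 4 that mix the genotypes passed a median of 7 lists. The p-values of limma's tests per row measure spread between embryos. Camera with the preset correlation compares genes with genes, the F test of usage pools a gene's probe sets, and Fisher's exact tests count genes. Their p-values do not measure spread between embryos alone. The F test of usage called 50.5% of genes with 1 probe set changed 2-fold, along with 106 unchanged genes of 10277. A second usage test, added after seeing that, compares each probe set minus its gene's mean with its own variance. It called 40.5% of the changed genes and 5 unchanged ones.

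Alternatives covered scaling, filters on dim rows, rows with 1 symbol, eBayes with trend and robust options, array weights, sex by Y-linked signal, the letter of the sample code as a random block, the replicate number as a block, and each replicate left out in turn. After seeing the data, 3 were added: leaving out the 100 genes on either side of Wt1, the mean of the proximal tubule list per array as a covariate, and the usage test with its own variance. Tables were handled with data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9 in Python 3.11.15.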

Results

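Glomerular RNA of 4 wild-type and 4 wt1(+KTS) mutant embryos late in gestation was compared on exon arrays. WT1 is a zinc finger protein made by podocytes, the epithelial cells of the glomerular filter, with or without an insert of the amino acids KTS; the labels name the mutants after Frasier syndrome, in which the form with the insert is reduced. The comparison addresses which transcripts differ in glomeruli when this form is altered. At the gene level the correlation between arrays was 0.938 to 0.960 within the mutants and 0.876 to 0.946 within the wild type. Wild-type replicate 4 stood apart, with correlations of 0.869 to 0.918 to the other arrays. The remaining wild-type arrays correlated at 0.937 to 0.946. Both genotypes held 2 arrays with high and 2 with low signal of Y-linked genes. Xist, named after its values were seen, stood at 12.56 to 12.85 in the low arrays. In the high arrays it stood at 7.90 and 4.63 (wild-type replicates 2 and 4) and 7.38 and 5.40 (mutant replicates 2 and 3). The cause of that spread was not tested.

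The first question was whether the level of Wt1 itself differed. Wt1 (transcript cluster 6879691) had a mean log2 signal of 9.01 ± 0.066 (SD, n = 4) in the wild type and 8.91 ± 0.11 (SD, n = 4) in the mutants. The difference of −0.11 ± 0.11 (SE) did not exceed the spread between embryos (exact permutation p = 0.2, two-sided; smallest possible 0.0286). Its 95% interval ran from −0.35 to 0.14. Of 20 Wt1 probe sets limma called 0, and 2 had an unadjusted p under 0.05. Their differences ran from −0.51 to 0.32. No probe set is known here to lie in the KTS insert, so these values do not test the splice change and do not check the genotype labels.

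Across all genes the next question was which transcripts were higher or lower in the mutants. Serpina6 (transcript cluster 6803219), which encodes corticosteroid-binding globulin, had the largest difference of the named genes. It fell by 4.24 ± 0.44 on the log2 scale (SE, n = 4 per genotype, adjusted p = 0.00423), from a mean of 11.19 ± 0.44 (SD) to 6.95 ± 0.995. Kcna1 (transcript cluster 6957244), a voltage-gated potassium channel, rose by 2.89 ± 0.18, or 7.41-fold (adjusted p = 0.000838); its other 2 clusters differed by 1.27 (not called) and 1.36 (called). The chemokines Cxcl10 and Cxcl11 rose 5.72-fold and 5.68-fold. Cd74, the invariant chain of MHC class II, rose 5.02-fold and the class II chain H2-Aa 3.51-fold.

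Other genes that rose most were Sprr2f (4.90-fold) and Sprr2g (4.53-fold), small proline-rich proteins of epithelia, Bloc1s6 (4.75-fold), a subunit of the BLOC-1 complex of lysosome-related organelles, and Gsdmc2 (4.10-fold), a gasdermin. Mucl3 rose 3.98-fold, Pmaip1, the pro-apoptotic protein Noxa, 3.79-fold, and Gabrp, a GABA receptor subunit, 3.68-fold. Among the genes that fell, Slc22a30, of the organic ion transporter family, was 5.14-fold lower, and Cd59b, an inhibitor of complement, 4.37-fold lower. Thsd7a, a podocyte membrane protein, was 3.54-fold lower (log2 −1.83 ± 0.16 SE, adjusted p = 0.00194). Tdrd5 was 3.71-fold lower, C430014B12Rik 3.71-fold, Nell2 3.59-fold, Acsm1, an acyl-CoA synthetase, 3.29-fold, and C1qtnf1 3.12-fold. Serpinf2, which encodes alpha-2-antiplasmin, was 3.07-fold lower, Sgip1 3.02-fold and Ms4a2, a chain of the IgE receptor, 2.98-fold. The remaining 3 clusters of Sgip1 were not called. A second called cluster differed by 0.59 for Bloc1s6 and by −0.89 for Ms4a2, less than the clusters named. By the naming rule, all 4 mutant values of each of these 24 genes lay on one side of all 4 wild-type values. The same was true of all 774 called clusters. Leaving out each of the 8 arrays in turn, 22 of the 24 kept their call throughout, while Cxcl11 and Bloc1s6 each lost it in 7 of the 8 runs (highest adjusted p 0.0977 and 0.136).

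**Figure D1:**
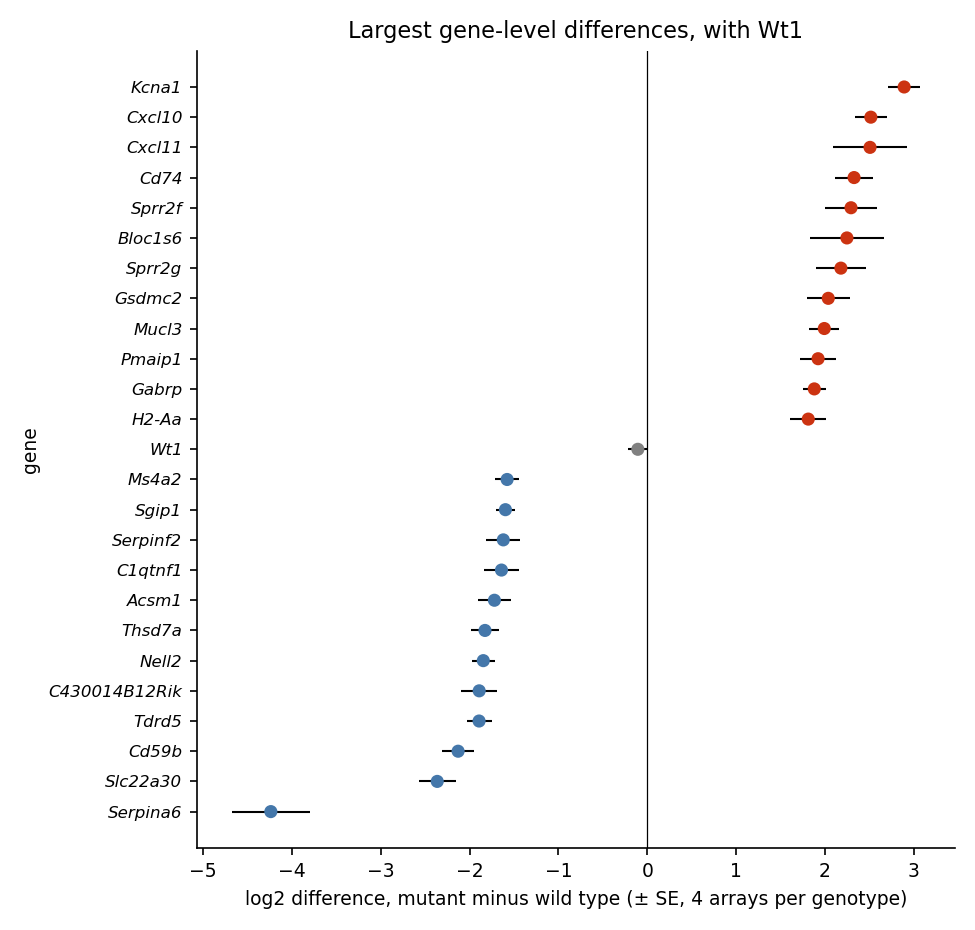
Log2 difference, mutant minus wild type (x axis, bars are SE, 4 arrays per genotype), of Wt1 and the 24 named genes (y axis). Differences run from −4.24 for Serpina6 to 2.89 for Kcna1, and Wt1 lies at −0.11.

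In all, limma called 774 of 93623 transcript clusters (0.827%), 315 higher and 459 lower in the mutants; the majority turned to the higher side with 1-symbol clusters alone (36.8% lower) and with the mean of probe sets (26.4% lower). Of the 774, 294 carried 1 symbol (171 higher, 123 lower), 23 several and 457 none, and 376 differed at least 2-fold. Genotypes did not overlap in 9.54% of all clusters, where chance gives 2.86%. An unadjusted p under 0.05 was found for 13347 clusters. The count fell to 259 with the letter of the sample code as a random block and rose to 1311 with array weights, 1408 with 1-symbol clusters alone and 2102 with the mean of probe sets. It was 324 without wild-type replicate 1, 268 without wild-type replicate 2, and 393, 315, 285 and 382 without mutant replicates 1 to 4.

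Gene lists fixed in advance were then tested for shifts as groups. The preset correlation passed 12 of 25, but another split of the arrays, which mixed the genotypes, also passed 12. Genes of the podocyte slit diaphragm and foot process fell (camera adjusted p = 7.84e-09; 0.191 with an estimated correlation). Of 43 measured members, 9 were called lower, 1 higher and 33 not called; adjusted over the list alone, 15 were lower and 2 higher. Next to Thsd7a, falls were found for the chloride channel protein Clic3 (log2 −1.46 ± 0.16 SE) and the receptor phosphatase Ptpro (−1.27 ± 0.12). Sema3g (−1.15), the cell cycle inhibitor Cdkn1c (−1.06), Clic5 (−0.80), Itgb5 (−0.64) and Pla2r1 (−0.59) fell less. Ptgds, prostaglandin D synthase, rose by 1.45 ± 0.15. Of the 10 called members 6 kept their call whichever array was left out, and Clic5, Cdkn1c, Itgb5 and Pla2r1 did not (highest adjusted p 0.0905, 0.0912, 0.0993 and 0.152). The lists of podocyte transcription factors (1 of 19 called, Hey1, higher by 0.79, a call lost in 6 of the 8 runs that left out 1 array, with a highest adjusted p of 0.098; list adjusted p = 0.490) and of WT1 targets from earlier work did not pass. Of 36 measured targets 4 fell, namely Col4a3, Ptpro, Col4a4 and Cdkn1c (list adjusted p = 0.207, median −0.0099, mean −0.097); adjusted over the list alone, 7 fell and 3 rose.

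Col4a3 and Col4a4, chains of the collagen IV network of the mature glomerular basement membrane, fell by 1.38 ± 0.12 and 0.96 ± 0.098 on the log2 scale. They were the 2 called members of 25 in the basement membrane list (camera adjusted p = 0.0164; 0.707 with an estimated correlation), and the same 2 adjusted over the list alone; both kept their call whichever array was left out. Nid2 and Lama5 differed by −0.35 and −0.32 without passing. The list lost its call without wild-type replicate 3 (adjusted p = 0.0841) and without mutant replicate 1 (0.174). Among angiogenic and guidance signals, the semaphorins Sema3e (−1.50 ± 0.11) and Sema3g fell and the other 24 of 26 members were not called; adjusted over the list alone, 5 fell and 2 rose. Vegfa (−0.47) and Adm (−0.78) missed the threshold. This list passed camera (adjusted p = 0.0192; 0.642 with an estimated correlation), but not without wild-type replicate 1 (0.0554) or 3 (0.0841).

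Glomerular endothelial genes fell as a group (camera adjusted p = 2.26e-13; 0.191 with an estimated correlation), and 32 of 35 were lower. The median was −0.30. Only Ehd3, an endocytic protein, was called (−1.26 ± 0.14); adjusted over the list alone, 17 fell and 1 rose. The VEGF receptor gene Kdr (−0.61), Pi16 (−0.81) and Icam2 (−0.50) missed the threshold over all rows.

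**Figure D2:**
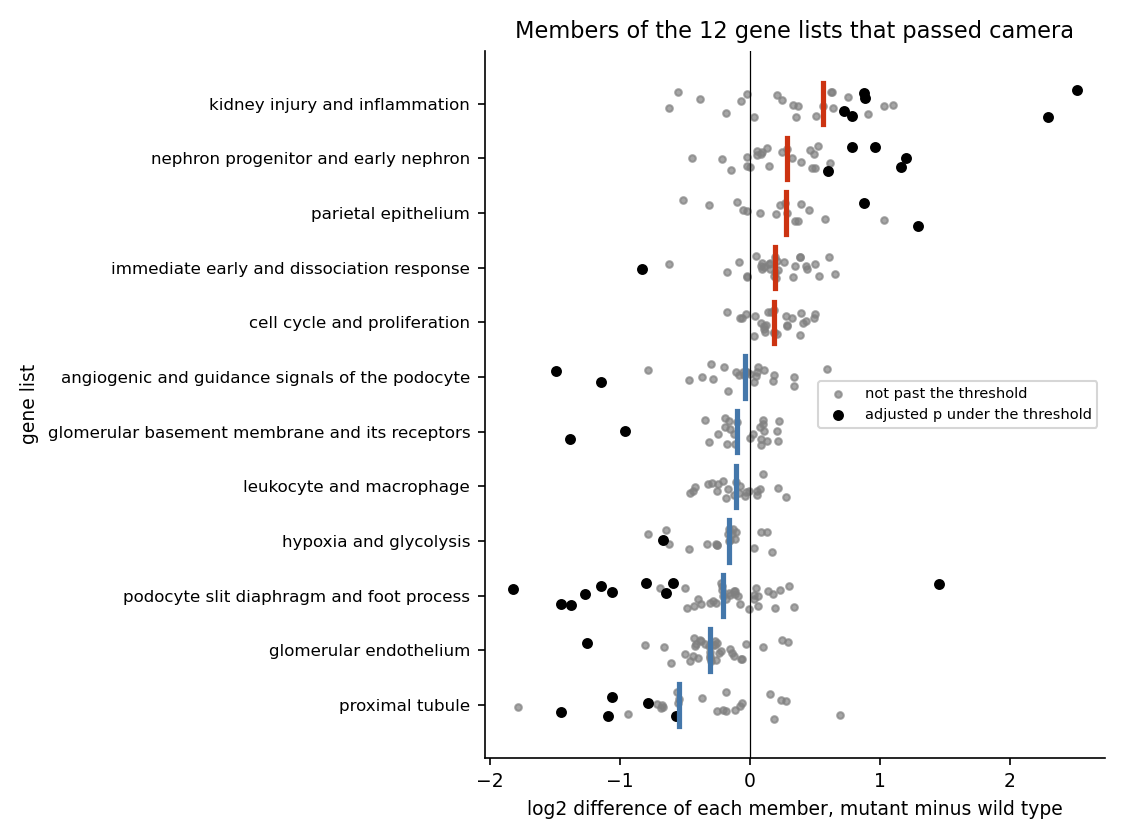
Log2 difference, mutant minus wild type (x axis), of each member of the 12 lists that passed camera with the preset correlation (y axis). Points are genes, black where called, and coloured lines are list medians, from −0.55 for proximal tubule to 0.57 for kidney injury.

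Kidney injury and inflammation genes rose (camera adjusted p = 1.4e-06; 0.191 with an estimated correlation), with a median of 0.57. Of 27 members 6 were called, all higher, and adjusted over the list alone 16 rose and 2 fell. Next to Cxcl10 and Sprr2f these were Sprr1a (0.89 ± 0.12 SE), the hyaluronan receptor Cd44 (0.87 ± 0.12), the TWEAK receptor Tnfrsf12a (0.79 ± 0.14) and the galectin Lgals3 (0.73 ± 0.13). Cd44, Tnfrsf12a and Lgals3 lost their call in 4, 7 and 8 of the 8 runs that left out 1 array (highest adjusted p 0.061, 0.127 and 0.127). In the parietal epithelium list Krt19 (1.30 ± 0.13) and Cd44 rose, 2 of 18 members (adjusted p = 0.00439; 0.236 with an estimated correlation), and 7 rose and 1 fell adjusted over the list alone. Vcam1 (1.03) and Wnt16 (−0.51) missed the threshold.

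Nephron progenitor and early nephron genes rose (camera adjusted p = 2.33e-06; 0.0928 with an estimated correlation). Of 27 members 5 were called, all higher, and adjusted over the list alone 14 rose and 1 fell. Meox2 rose by 1.20 ± 0.13 and Eya1 by 1.17 ± 0.12 (SE). Six2, a transcription factor that keeps nephron progenitors undifferentiated, rose by 0.96 ± 0.11, Crym by 0.79 ± 0.12 and Uncx by 0.60 ± 0.097. Crym and Uncx lost their call in 5 and 7 of the 8 runs that left out 1 array (highest adjusted p 0.0728 and 0.0986). The mean of the list was 7.74 to 7.81 in the mutants and 7.41 to 7.49 in the wild type.

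**Figure D3:**
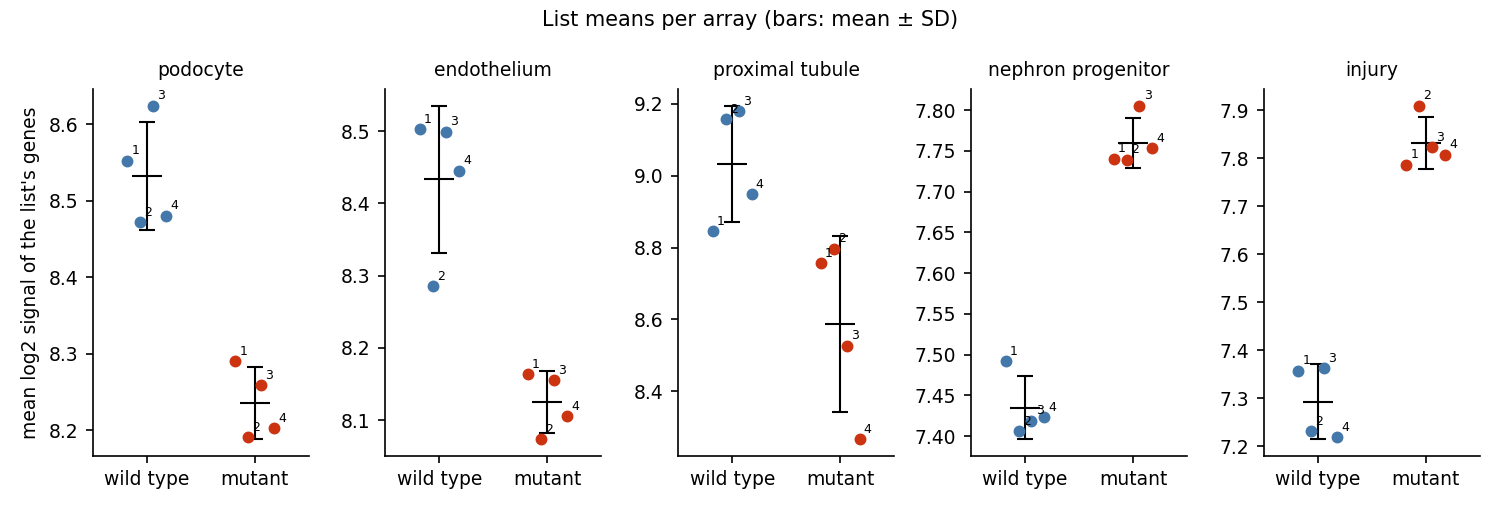
Mean log2 signal of 5 gene lists (y axis, not starting at 0) in each array (points, labelled by replicate number), by genotype (x axis), with mean and SD as bars. The nephron progenitor means were 7.41 to 7.49 in the wild type and 7.74 to 7.81 in the mutants.

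Lists of other kidney cells gave mixed results. Proximal tubule genes fell (camera adjusted p = 7.84e-09; 0.468 with an estimated correlation), with a median of −0.55. Of 27 members 5 were called lower, the transporters Slc13a3 (−1.46 ± 0.21 SE), Slc34a1 (−0.79 ± 0.14) and Slc5a2 (−0.57 ± 0.11), the peptidase Dpep1 (−1.09 ± 0.13) and the scaffold Pdzk1 (−1.06 ± 0.16); adjusted over the list alone, 13 fell and 1 rose. Dpep1 kept its call whichever array was left out, while Slc13a3, Pdzk1, Slc34a1 and Slc5a2 lost it in 3, 6, 7 and 7 of 8 runs (highest adjusted p 0.0671, 0.0838, 0.117 and 0.155). Their list mean was 8.27 to 8.80 in the mutants and 8.85 to 9.18 in the wild type, so it was lower in the mutants, as the podocyte and endothelial lists were. Within the wild type it did not follow the endothelial list: replicate 1 was lowest for proximal tubule (8.85) and highest for endothelium (8.50). The loop, distal tubule and collecting duct list did not pass (adjusted p = 0.729); Hsd11b2 rose by 0.79 ± 0.11 (adjusted p = 0.0542 in 1 of 8 runs that left out an array). Leukocyte genes were lower as a group (median −0.10, adjusted p = 0.00596; 0.642 with an estimated correlation), with 0 of 23 called by limma, 3 at an unadjusted p under 0.05, 2 lower adjusted over the list alone, and no list call without mutant replicate 1 (0.0967). Cd53, Csf1r, S100a8 and Ptprc differed by −0.43, −0.44, −0.46 and −0.24.

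Hypoxia and glycolysis genes fell (median −0.16, adjusted p = 5.5e-05; 0.468 with an estimated correlation), with Pgk1, a glycolytic kinase, called (−0.67 ± 0.12 SE) and Pgam1 (−0.62), Adm and Vegfa short of the threshold; adjusted over the list alone, 4 fell. Cell cycle genes rose as a group (median 0.19, adjusted p = 0.00222; 0.642 with an estimated correlation), with limma calling 0 of 27 and 9 at an unadjusted p under 0.05; adjusted over the list alone, 6 rose. Ccne1, Mcm5, Kif20a and Mcm2 differed by 0.50, 0.43, 0.41 and 0.39. Immediate early genes rose as a group (median 0.19, adjusted p = 0.00318; 0.642 with an estimated correlation), although the called member, the matricellular gene Ccn2, fell by 0.83 ± 0.16; adjusted over the list alone, 5 rose and 1 fell. Pgk1 and Ccn2 each lost their call in 7 of the 8 runs that left out 1 array (highest adjusted p 0.138 and 0.136). Gadd45b, Atf3 and Ier5 differed by 0.66, 0.44 and 0.43.

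The other lists did not pass. The adjusted p was 0.0880 for mesangium, pericytes and renin cells, 0.532 for stroma, 0.580 for erythroid genes, 0.599 for Notch, 0.691 for Wnt, 0.150 for FGF, BMP and TGF-beta signalling, 0.130 for actin regulators, 0.590 for splicing factors, 0.0847 for sterol synthesis and 0.888 for sex-linked genes. Of these, 3 passed when 1 array was left out: mesangium without wild-type replicate 2 (0.0255) or mutant replicate 1 (0.0343), actin regulators without wild-type replicate 4 (0.0115), and sterol synthesis without wild-type replicate 4 (0.00164) or mutant replicate 1 (0.00652). Within them Dkk2, a Wnt antagonist, fell by 0.76 ± 0.10, Fgf1 by 0.68 ± 0.12 and Arhgap28, a regulator of the actin cytoskeleton, by 0.67 ± 0.12 (SE). These lost their call in 3, 8 and 7 of the 8 runs that left out 1 array (highest adjusted p 0.0548, 0.112 and 0.119). Signs differed in 3 lists: erythroid (median 0.0043, mean −0.0040, test downward), Wnt (median −0.0090, mean 0.026, test downward) and sex-linked (median 0.28, mean 0.23, test downward). With an estimated correlation camera passed 0 of 25 lists, 5 had an unadjusted p under 0.05, and fry passed 5.

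The exon-level table asked the same question per probe set. Limma called 10035 of 375483 probe sets (2.67%), 5475 higher and 4560 lower, and 6890 of them lay in 2846 genes with 1 symbol. The share of lower probe sets, 45.4%, was not stable: it was 32.0% with 1-symbol probe sets alone, 50.7% with quantile normalization again, 35.8% without wild-type replicate 3, 50.7% and 52.8% without wild-type replicates 2 and 4, and 50.2%, 50.3% and 51.2% without mutant replicates 1 to 3. These are the same arrays, so this is not independent of the gene level. Across 17157 genes, which are not independent replicates, the mean of a gene's probe sets and its cluster gave differences that correlated at 0.923, and 257 of 258 called genes had the same sign. The count fell to 2870 with the letter of the sample code as a random block and rose to 16875 with trend and robust options and 15378 with array weights. It was 4529 and 3513 without wild-type replicates 1 and 2, and 4820, 4091, 3556 and 5375 without mutant replicates 1 to 4.

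Exon usage asked whether single probe sets departed from their gene. Tcp11l1, on chromosome 2 as Wt1 is, had the smallest p: 1 probe set fell from 9.22 ± 0.18 to 5.52 ± 0.46 (SD, n = 4), a usage value of −3.43, while the gene differed by −0.30 (adjusted p = 0.232). In Cd59a, also on chromosome 2, a probe set fell from 9.55 ± 0.52 to 5.06 ± 0.24, a usage value of −2.51. In Fxyd2, a modulator of the sodium pump, one fell from 10.16 ± 0.34 to 6.10 ± 0.80, a usage value of −3.685. The gene itself differed by −0.84 (adjusted p = 0.0302). In Actn3, an actinin on chromosome 19, a probe set rose from 6.11 ± 0.52 to 10.53 ± 0.33, a usage value of 2.46. This gene also rose, by 1.74 (adjusted p = 0.000838). Sf3b2 and Sf3b3, splicing factors, had usage values of −1.72 and 1.20, Pola2 0.99, Ubr1 −1.64 and Eya1 1.51. Pola2 and Sf3b2 lay on chromosome 19, as Actn3 did. Of 368 tested genes on that chromosome, 4.35% had a call by the second usage test, with own variances. The Col4a3 probe set with a usage value of 2.38 itself differed by 0.20 (adjusted p = 0.770) while its gene fell.

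In all, the F test called 2830 of 10274 genes, and the Simes test 2640, with 2186 by both. The test with each probe set's own variance, added after seeing the simulated calls, called 459, 377 of them also by F. Of the 10 genes named by the rule it called all but Ubr1 (adjusted p = 0.0629). Wt1 passed the F test (adjusted p = 0.0229, rank 2133) but not that one (0.198). The exon usage calls by F numbered 1496 without wild-type replicate 2 and 1475, 1520 and 1446 without mutant replicates 1 to 3.

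Calls were placed unevenly along the genome. Of the 119 tested genes within 100 genes of Wt1, 45.4% had a usage call by F, and 26.9% of 9432 on other chromosomes did (Fisher's exact p = 1.69e-05, two-sided). With own variances the shares were 13.4% and 4.21% (Fisher's exact p = 5.01e-05). At the gene level 6 genes from 50 before to 50 after Wt1 were called, 5.94% against 1.42% elsewhere. Named after their values were seen, they were Cd44, Pamr1, Prrg4 and Wt1os, which rose, and Cd59b and Them7, which fell. Windows without Wt1 that held at least 6 calls numbered 87 of 16290, and chromosomes 3, 9 and 17 each had some with 6. In gene order over both levels, the usage share by F was 44.1% within 50 genes of Wt1, 46.7% in the next 50 on either side and highest, 52.9%, in the 100 after those, where gene-level calls made up 6.32%, 1% and 1.10%. With own variances the usage shares of these bands were 16.9%, 10% and 15.7%, highest next to Wt1. Bloc1s6 and Ubr1, also on chromosome 2, lay in the last of them. All 11 own-variance calls in that band lay after Wt1 in gene order, from Tyro3 at 105 genes to Wdr76 at 146. Most F calls of the band lay on that side too, where more of its genes were tested. The window was chosen after seeing the data.

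**Figure D4:**
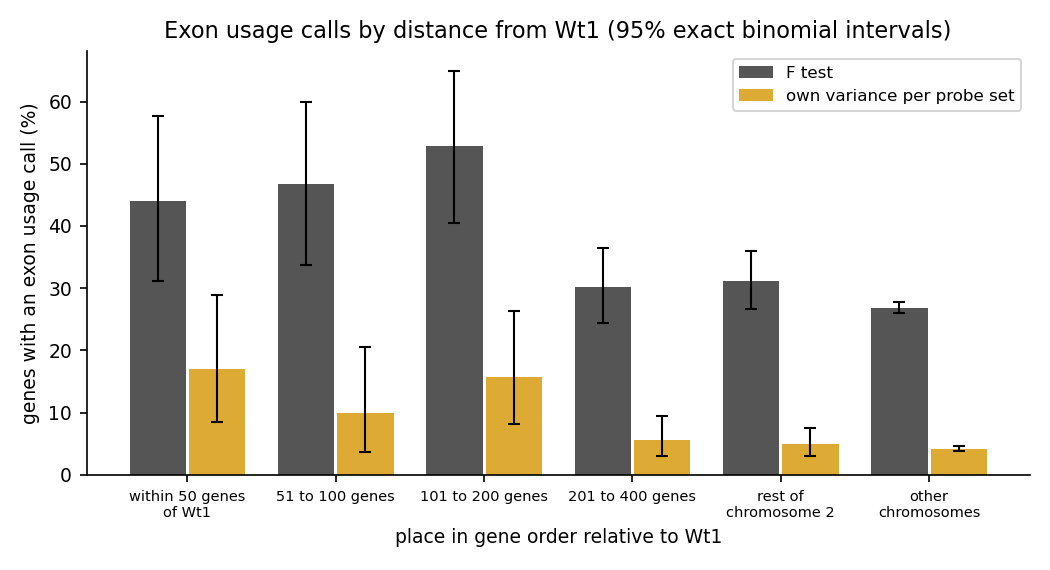
Percent of tested genes with an exon usage call (y axis) by place in gene order relative to Wt1 (x axis), for the F test and for own variances, with 95% exact binomial intervals. By F the share was 44.1% within 50 genes of Wt1, 52.9% at its highest farther out on the chromosome and 26.9% on other chromosomes.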

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

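The tests of replicate 4, of podocyte share, and of tubules of every segment were chosen only after the result was seen, and the covariate after seeing the data. The test of podocyte share replaced a first version after that one's result was seen: the median of the restricted genes, −0.38 (95% interval −0.69 to −0.11), against that of the called ones, −1.15, which is extreme by selection.

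Of 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many gene-level calls (774 against at most 52 in another split). The same held for exon-level calls (10035 against 135) and usage calls (2830 against 1167). This argues against chance but does not exclude it, since 1 of 35 is the smallest share that these splits can give. A difference tied to the letter of the sample code could also peak in the real split, as no letter occurs in both genotypes. For the gene lists the real split was not alone: 2 of the 35 splits gave 12 passed lists, the real one and one that mixes the genotypes, and 12 is also the highest among the others. By list, the real split alone gave the smallest p for the podocyte, parietal, nephron progenitor and injury lists, while, counting the real split, 2 of the 35 gave a p as small for endothelium, 6 for proximal tubule, 6 for hypoxia, 7 for angiogenic signals, 8 for cell cycle, 11 for immediate early genes, 11 for leukocytes and 14 for basement membrane.

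In 14 of 124 groups of 4 values, 1 array lay far from the other 3, by the ratio of its gap to the whole range. Chance gives about 1 in 20, or 6.2 here. Wild-type replicate 4 was the distant array for Bloc1s6 (ratio 0.902; 6.98 against 5.10 to 5.28), Sprr2g (0.899; 5.96 against 4.98 to 5.08), Ptgds (0.951; 5.97 against 5.66 to 5.67), Pgk1 (0.929; 6.38 against 6.52 to 6.53) and Pla2r1 (0.89; 7.03 against 7.20 to 7.22). Wild-type replicate 3 was for Tdrd5 (0.856; 9.08 against 8.75 to 8.80), Col4a4 (0.927; 7.43 against 7.31 to 7.32) and Cd44 (0.857; 6.66 against 6.471 to 6.498), and wild-type replicate 2 for Cd59b (0.933; 7.08 against 7.72 to 7.77). Among the mutants it was replicate 2 for Ptpro (0.931; 7.20 against 7.41 to 7.42) and Sema3e (0.849; 5.54 against 5.67 to 5.69), replicate 1 for Kcna1 (0.872; 8.22 against 7.69 to 7.76), replicate 3 for Pgk1 (0.892; 6.09 against 5.71 to 5.75) and replicate 4 for Gabrp (0.874; 8.41 against 8.72 to 8.77).

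Podocyte genes fell. Wild-type replicate 4 as the cause is argued against, since 8 of the 9 podocyte genes called lower kept their call without it. A smaller share of podocytes as the whole cause would move all podocyte-restricted genes by about the same amount. Over 23 genes listed as such, the variance of the log2 differences was 18.4 times the mean squared standard error. That does not settle the question, since the genes were listed after the values were seen. Whether each is confined to podocytes here was not tested. Compression of dim probes can add to the spread and was not separated. Of the 23, 19 were lower and 4 higher. Thsd7a stood at −1.83 ± 0.16 (SE), while Wt1 stood at −0.11 ± 0.11 and, chosen after their values were seen, Podxl, the brightest member, at −0.29 ± 0.12, Tcf21 at −0.055 ± 0.12 and Foxc2 at 0.30 ± 0.14. A lower share as the whole or part of the cause, and an effect of the mutation on single podocyte genes, which is a hypothesis, stay open.

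Proximal tubule genes fell as a list with the preset correlation but not with an estimated one (camera adjusted p = 0.468). Less carry-over of tubules of every segment is argued against by the loop, distal and collecting duct list, whose median was 0.021 (95% interval over genes −0.16 to 0.30). Less carry-over of proximal fragments alone would move all proximal genes alike, but their variance was 7.98 times the mean squared standard error, with Slc13a1, named after its value was seen, at 0.69 ± 0.18 (SE). That does not settle the question, since whether each gene is confined to proximal tubule here was not tested. Compression of dim probes can add to that spread and was not separated. The proximal mean per array was also used as a covariate. The endothelial median was then −0.34 (interval −0.39 to −0.27) and the podocyte median −0.16 (interval −0.30 to −0.011), both below 0. These intervals are over genes, not arrays. The median standard error of a gene in that run was 0.196 for the endothelial list and 0.205 for the podocyte list. The covariate also followed genotype (r = −0.778). The run therefore cannot decide whether tubule content is the whole cause of the fall of these lists. For the fall of the proximal genes, maturation of the tubules in the mutants, and less carry-over of proximal fragments as the whole or part of the cause, stay open.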

How the results depend on the processing

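The tubule covariate, the run without genes near Wt1 and the own-variance usage test were chosen after seeing the data. The level of Wt1 stayed uncalled in every alternative (−0.14 to −0.060 leaving out 1 replicate each). Gene-level calls rose to 1199 with rows at or above the median mean, 1408 with rows of 1 symbol (36.8% lower against 59.3%), which test fewer rows, to 2102 with the mean of exon-level probe sets (26.4% lower), which changes the summary too, and to 1311 with array weights. They fell to 259 with the letter as a random block. Arrays that share a letter were correlated (consensus 0.17), which widens the error of the genotype difference. No letter occurs in both genotypes, so an effect of genotype cannot be told apart from whatever the letter marks. With the tubule covariate 5 were past the threshold: the median absolute log2 difference of the 774 calls moved from 0.99 to 0.98 with all signs kept, and the median standard error from 0.15 to 0.23, because the covariate follows genotype. Without the genes near Wt1 there were 757. With each array centred on its median there were 604 (51.3% lower), and 49 of the 59 called genes that the naming rule chose kept their call. Leaving out replicates, with fewer samples, gave 268 to 758 calls; without wild-type replicate 4, 553 of 758 were shared.

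Exon-level calls rose to 16875 with trend and robust options and 15378 with array weights, and the cause was not tested. They fell to 2870 with the letter block, where the consensus correlation within a letter was 0.19. They were 3513 to 9913 leaving out replicates. Usage calls were 1446 to 3890 leaving out replicates and 459 with own variances.

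The labels give no pairing of the embryos, so the replicate numbers were not taken as pairs. Same-numbered arrays had deviations correlated at −0.0048, 0.069, 0.263 and 0.204 at the gene level and −0.00076, 0.117, 0.236 and 0.200 at the exon level; 2 of 4 wild-type arrays correlated best with their own number at the former and 3 of 4 at the latter, a hint from the data only. With the replicate block there were 185 gene-level calls, 163 of them shared, and 7859 exon-level calls, and 30 of the 59 called genes that the naming rule chose kept their call.

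With an estimated correlation 0 lists passed, against 12. The adjusted p was 0.191 for podocyte, endothelium and injury, 0.707 for basement membrane, 0.236 for parietal, 0.468 for proximal tubule and hypoxia, 0.0928 for nephron progenitor, and 0.642 for leukocyte, cell cycle, angiogenic and immediate early genes. Leaving out replicates gave 10 to 14 lists, with ranges of 0.00084 to 0.174 for basement membrane, 0.0012 to 0.0967 for leukocytes and 0.0051 to 0.0841 for angiogenic signals. The immediate early list had 0.080 with the tubule covariate. Among lists not passed, mesangium passed with rows at or above the median mean (0.0244) and the tubule covariate (0.0313), sterol synthesis with the former (0.0412) and stroma with the latter (0.045). Lists not passed also turned direction: stroma (0.138 to 0.932), erythroid (0.249 to 0.981), splicing (0.174 to 0.902) and sex-linked (0.672 to 0.981; 0.967 with all 1-symbol clusters, 0.829 with the tubule covariate). Of single genes, 3 turned: Lum with the tubule covariate (−0.047), Arhgef3 (0.36) and Elovl6 (0.062) with the mean of probe sets; the cause was not tested. Of the 59 called genes that the naming rule chose, 37 (without wild-type replicate 2) to 50 (without wild-type replicate 4) kept their call leaving out replicates, 40 did with the letter block and 1 with the tubule covariate.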

Other observations

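The lists in the next paragraph and the leukocyte test were chosen only after the result was seen, as was the test of where calls lie along the chromosomes. Both usage tests of the Wt1 neighbourhood were run with own variances, then moved to the main usage test after those results were seen; with own variances the ratio was 3.19, and 53.6% of 28 probe sets against 52.7% were lower (one-sided Fisher's exact p = 0.541).

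Claudins, which set the permeability of tight junctions, included 4 called members of 18, all higher: Cldn3 (1.47 ± 0.22 SE), Cldn9 (1.37 ± 0.14), Cldn4 (1.03 ± 0.11) and Cldn7 (0.92 ± 0.13). Among 28 chemokines and TNF family genes 5 were called, all higher, with Cxcl16 at 1.70 ± 0.18, Tnf at 1.39 ± 0.18 and Cxcl2 at 0.65 ± 0.10 next to Cxcl10 and Cxcl11. In MHC class II presentation 3 of 7 were called, all higher, Cd74, H2-Aa and H2-Ab1 (1.03 ± 0.17). Of 14 complement genes 3 were called: Cd55 (−1.04 ± 0.11) and Cd59b fell and C2 rose (0.72 ± 0.12). Of 28 interferon-induced genes 2 were called higher, Cxcl10 and Cxcl11, and limma called 0 lower; 18 had a negative and 10 a positive difference, with a median of −0.13. As these lists were drawn after seeing called genes, their counts are not evidence of enrichment.

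A hypothesis for the rise of Cd74, H2-Aa and Cxcl10 is more leukocytes in the mutant preparations. The fixed leukocyte list argues against it. Its median was −0.10 (95% interval −0.21 to −0.032, over genes and not arrays), and its 4 brightest members in the wild type, named after their values were seen, Cd68, Laptm5, Fcer1g and C1qb, stood at −0.18 ± 0.17, −0.12 ± 0.12, −0.036 ± 0.13 and −0.0076 ± 0.15 (SE), against 2.33 ± 0.22 for Cd74. A fall of leukocytes is not claimed, since the list's call was lost with an estimated correlation (0.642) and without mutant replicate 1 (0.0967), and 11 of 35 splits, the real one included, gave a p as small. Leukocytes that the list does not mark, and the cell type that carries these transcripts, stay open.

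Around Wt1, 6 genes among the 50 on either side were called, against a mean of 1.47 over 10000 shuffles. The highest count of any such window, 7, occurred only on chromosome 2, in windows centred between Chst1 and Emc7, a span that holds Wt1. Chance placement still cannot be told apart from linkage by these counts. The window was chosen after the calls were seen, shuffling treats neighbouring genes as independent, and 87 overlapping windows without Wt1 held at least 6 calls. On a mixed background, a chromosome segment of another strain linked to the mutated allele may differ between the genotypes and change probe binding or expression in cis, and the ratio of 1.69 in the share of usage calls near Wt1 is consistent with it. If the mutants alone carried variants that weaken probes, deviating probe sets near Wt1 would more often be lower in them, but 41.8% of 98 were, against 36.2% of 3609 on other chromosomes (one-sided Fisher's exact p = 0.149), so this part cannot be told apart with so few probe sets, as the reference strain of the segment is not given. For genes near Wt1, among them Cd59b, Cd44, Tcp11l1 and Cd59a, and for Bloc1s6 and Ubr1 farther out, linkage and an effect of the mutation both stay open; a run without the 100 genes on either side, which leaves those 2 in, gave 757 gene-level calls.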
